A study of Mus musculus with 193 samples.

How the data were processed

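Single-cell RNA-seq was deposited for 193 mouse testis cells that had been sorted for green fluorescence from an Id4-eGFP reporter. Each deposited sample was 1 cell. Per the labels' protocols, cDNA was made from single cells on a Fluidigm C1 chip with SMARTer chemistry, ERCC spike-in RNA was added at lysis, and libraries were made with Nextera XT. The submitters' processing notes name STAR 2.3.0, HTSeq 0.6.1 and the mouse genome build mm10, without stating the role of each. The gene annotation, the strand setting and the treatment of reads that align to several places are not given in the sources used here.

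The deposited table holds 1 value per gene and cell and is named as TPM, but the values behaved as RPM. In each cell the deposited RPM values were whole multiples of 1 step that was the same for every gene, so they carry no gene length term. With a tolerance of 0.001 RPM, on average 100.0% of values came out as whole reads, and the lowest share in any cell was 99.99%. The total to which the values are relative was larger than the reads in the table: the table's rows summed to between 8.13% and 23.0% of the total per cell. What the other reads were is not stated. Reads were recovered by dividing each value by its cell's step. The plan, written before the data were examined, had assumed TPM, and the same measures were applied to RPM.

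The table has 19642 rows. Its 84 ERCC rows and Rn45s, the precursor of ribosomal RNA, were kept out of the gene comparisons. All 193 columns matched 1 sample each by name. No 2 cells had identical columns, and the highest correlation between any 2 cells was 0.671 (log2 values, across genes). The recovered total per cell ranged from 251530 to 10663507 reads, and the reads on genes from 25424 to 1373776. Genes such as those of glycolysis and the ribosome, which have many pseudogene copies, can be listed too low where reads with several alignments were left out.

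Cells are not replicates of a condition. The labels name no animal, litter or culture, so each of the 3 groups counts as 1 sample. No p-value, standard error or number of changed genes was therefore computed, and a count test on the recovered reads was not run. The sample titles carry letters that the labels do not explain. They divide the cells into 7 lettered sets, which served only to show how far a difference repeats. The value of a group is the unweighted mean of its sets' means over cells of log2(RPM + 1), with a pseudocount of 1. Differences are on that scale, which understates the change of genes with low values. Beside a difference stands the range over all pairs of a set from each group, 6 pairs for P3 cells labelled KO against WT P3 and 4 pairs for WT P7 against WT P3. A split of the sets that has nothing to do with expression puts a gene on the same side in all pairs with a chance of 20% for the first comparison and 33.3% for the second. Ratios of mean RPM are given for some genes, again with sets weighted equally. Standard deviations given with levels are between cells. Shares of cells above 1 RPM have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

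The genes named in the text followed a rule fixed before the data were examined: Rhox10 and Id4, then the 12 highest and 12 lowest differences per comparison among genes with a mean level of at least 2 and the same sign in all pairs, without predicted or unnamed genes, and up to 2 highest and 2 lowest members of each gene list. Gene names outside this rule are marked as such, and 1 gene that the rule picks is not reported here. The 22 gene lists, also fixed before the data were examined, covered spermatogonial stem cell, progenitor, differentiating, prospermatogonial, pan germ cell and pluripotency genes, GDNF and FGF signalling, retinoid, migration, S phase, G2/M, glycolysis, oxidative phosphorylation, stress, p53 and apoptosis, and Rhox cluster genes, and markers of Sertoli, Leydig, myoid or stromal, endothelial, leukocyte and erythroid cells. Some lists share members, so their medians are not independent of each other. Members with a mean level of at least 0.5 in a comparison counted as measured. The median of each list was placed among the medians of 10000 random lists matched on level in 20 bins. That percentile describes these cells and is not a test. The range over pairs beside a list median is that of the list's medians in single pairs. The list median, taken over averaged differences, can lie outside it. Older gene symbols were matched through RefSeq synonyms.

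To place the cells labelled KO between the 2 ages, the 100 genes highest and the 100 lowest at P7 were picked from the sets of 1 letter, and scored as the mean of the first minus the mean of the second in the sets of the other letter. The position is 0 at the held-out WT P3 set and 1 at the held-out WT P7 set, averaged over both choices. The relation between the 2 comparisons across genes was computed with separate WT P3 sets on each side, and with shared ones beside 100 simulated draws of unchanged groups resampled from WT P3 cells.

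Alternatives were other pseudocounts (0.1 and 10), the log of mean RPM, equal weight per cell, 2 filters on cells, leaving out the cell without raw data, rescaling each cell to genes above 1 RPM in at least 90% of cells, other floors, other thresholds for shares of cells, other numbers of genes for the position, pairing of sets by letter, and leaving out each set. Added after seeing the data were scaling to reads on genes, thinning to 100000 reads on genes (5 WT P3 cells fell below this and were left out), sums of reads per set, other splits of the sets, and 5 further gene families. The procedure was tested on simulated data for the comparison of cells labelled KO with WT P3, run on 4920 genes with 50 genes seeded per fold size. Genes changed by a factor of 4 had the right sign in all 6 pairs in 96% of cases and those changed by a factor of 0.25 in 98%. At factors of 2 and 0.5 the shares were 72% and 68%. Unchanged genes had the same sign in all pairs in 16.9% of cases. The simulated sets of 1 label differed only by sampling of cells and depth. The real sets of 1 label differed by more, so these shares do not carry over to them. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Positions of named genes are from GENCODE vM21 on GRCm38, the assembly also called mm10.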

Results

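Single cells positive for Id4-eGFP, a reporter for a gene of spermatogonial stem cells, were profiled from mouse testes. There were 71 wild-type (WT) cells from postnatal day 3 (P3), 69 P3 cells labelled as knockout (KO) for Rhox10, and 53 WT cells from postnatal day 7 (P7). Rhox10 is an X-linked homeobox gene of the Rhox cluster. Sample titles split the cells into lettered sets of unstated meaning: WT P3 had set A with 16 cells and set B with 55, the cells labelled KO had set A with 21, set B with 12 and set C with 36, and WT P7 had set A with 12 and set B with 41. Median recovered totals per cell were 4425188 reads for WT P3, 4552353 for cells labelled KO and 3299782 for WT P7. The medians of genes above 1 RPM were 7073, 6992 and 6531. All 193 cells had Ddx4 or Dazl, markers of germ cells, above 1 RPM. The labels name no animals and do not explain the sets, so no test was made, and every difference describes these cells, with the range over pairs of sets as its only measure of repeatability.

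The targeted gene was examined first. Rhox10 (ENSMUSG00000053909.8, a protein-coding gene on chromosome X, 38066475 to 38071691, plus strand) had no lower mean level in the cells labelled KO as a whole. Its mean log2(RPM + 1) was 2.48 ± 1.57 (SD between cells, n = 21 cells) in their set A, 2.62 ± 1.47 (n = 12) in set B and 0.83 ± 1.09 (n = 36) in set C. WT P3 had 1.78 ± 1.51 (n = 16) in set A and 1.49 ± 1.11 (n = 55) in set B. The difference between the groups was 0.34, and the pairs ranged from -0.95 to 1.12. The share of cells above 1 RPM was 71.4% (95% interval 47.8% to 88.7%) in KO set A, 75% (42.8% to 94.5%) in set B and 27.8% (14.2% to 45.2%) in set C, against 62.5% (35.4% to 84.8%) and 63.6% (49.6% to 76.2%) in WT P3 sets A and B. Over all cells the share was lower in those labelled KO, at 49.3% (37.0% to 61.6%) against 63.4% (51.1% to 74.5%) in WT P3. Of the 3 KO sets, only set C had less Rhox10 than both WT P3 sets. The labels do not state which part of the gene was removed, and reads on a remaining part would still be listed. Because Rhox10 RNA was not lower in sets A and B, the term "labelled KO" is used throughout. Directions below are directions of these labels.

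**Figure D1:**
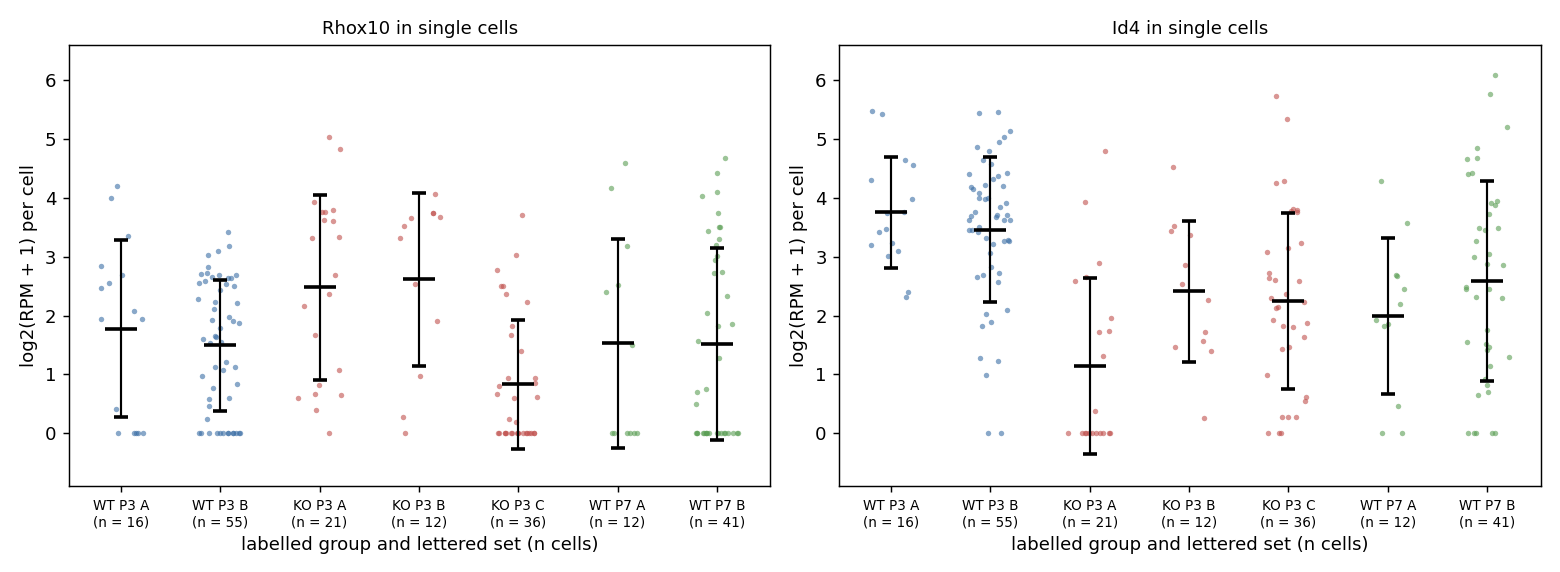
Rhox10 (left) and Id4 (right) as log2(RPM + 1) per cell on the vertical axis, by labelled group and lettered set on the horizontal axis. Points are cells, and black bars are the set mean with 1 SD between cells. Rhox10 means lie at 2.48 and 2.62 in KO sets A and B, above both WT P3 sets, while Id4 means are below both WT P3 sets in all 3 KO sets and both WT P7 sets.

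The study's labels set P3 cells labelled KO for Rhox10 against WT P3 cells. With Rhox10 RNA not lower in sets A and B, it is read here as a comparison of the labels. Whether the function of the gene was lost stays open. Id4 (ENSMUSG00000021379.2, protein-coding, chromosome 13, 48261228 to 48266026, plus strand), the gene of the reporter used for sorting, had the lowest difference among genes with a mean level of at least 2 and the same sign in all pairs. The difference was -1.67 (pairs -2.61 to -1.05). Mean RPM was 5.55 in cells labelled KO and 14.6 in WT P3, a ratio of WT to KO of 2.63. By set, Id4 was 1.14 ± 1.50 (n = 21), 2.41 ± 1.19 (n = 12) and 2.25 ± 1.50 (n = 36) in KO sets A, B and C, against 3.75 ± 0.94 (n = 16) and 3.46 ± 1.23 (n = 55) in WT P3. Cells above 1 RPM made up 68.1% (55.8% to 78.8%) of those labelled KO and 95.8% (88.1% to 99.1%) of WT P3. By set the share was 42.9%, 91.7% (61.5% to 99.8%) and 75% in KO sets A, B and C. It was 100% and 94.5% in WT P3 sets A and B, so KO set B was close to WT P3 in this measure. As cells were sorted on the Id4 reporter, its level also depends on the sort gate, which is not stated.

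Other genes lower in the cells labelled KO in all pairs included Lin28a, which encodes an RNA-binding protein of undifferentiated spermatogonia (-1.22, pairs -1.73 to -0.50), Map2k1, which encodes the kinase MEK1 (-1.30), Ctsa, a lysosomal protease (-1.37), and Trip13, which acts in meiotic recombination (-1.43, pairs -3.13 to -0.01). Abca1, a cholesterol exporter, differed by -1.28 and Atp2c1, a Golgi calcium pump, by -1.26. The others of the 12 lowest were Plekhh1, Yy2, Tmc7, Neb and Pitpna, between -1.34 and -1.29. Among the highest, Arrdc4, an arrestin-domain gene, had a difference of 1.87 (pairs 0.77 to 3.17), with a mean of 13.7 RPM against 1.58. Zfp367 differed by 1.73 (pairs 1.16 to 2.54), Myo9b, an unconventional myosin, by 1.54 (pairs 1.30 to 1.91), and Klf13, a Krüppel-like transcription factor, by 1.37 (pairs 0.96 to 1.93). The clock gene Per3 was higher by 1.29 (pairs 1.07 to 1.59), the translesion polymerase gene Rev1 by 1.28, and Ehmt2, which encodes the histone methyltransferase G9a, by 1.26 (pairs 0.55 to 1.87). Phf21a, Marveld2, Atp2b4, Mn1 and Maged1 completed the 12, between 1.28 and 1.61. All 24 genes kept their sign after rescaling to stably detected genes. They were picked for large differences, and rescaling shifted the median of all genes by 0.16, so this says little of their stability.

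Of 14 measured stem cell genes, 12 were lower in the cells labelled KO, 4 of them in all pairs, and none was higher in all pairs. The list's median was -0.50, with 0 of 10000 random lists lower. Bcl6b, a GDNF-responsive repressor, differed by -1.41 (pairs -2.24 to -0.33), and Pou3f1 by 0.25 (pairs -0.38 to 0.90). The list median depended on KO set A: the pairs ran from -1.65 to 0.19, and without that set the median was 0.21. In KO set A the mean level of the list was 1.54, against 2.93 and 3.09 in KO sets B and C and 3.12 and 3.04 in WT P3. Id4 and Bcl6b were lower in every pair, those without set A included. GDNF and FGF signalling genes gave a median of -0.15 over 19 genes (percentile 0.395), which became 0.44 without KO set A and -0.30 after rescaling. In this list Spry2, an inhibitor of receptor signalling, was higher (1.14, pairs 0.27 to 2.29), as was Mycn (0.87, pairs 0.29 to 1.28). The GDNF and FGF list shares genes such as Bcl6b and Pou3f1 with the stem cell list, so their medians are not independent.

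Progenitor genes showed no shared direction, with a median of -0.08 over 13 genes, and the median was 0.08 without KO set A and -0.20 after rescaling. Dmrt1 was at 0.73 (pairs -0.02 to 1.33). Of 13 measured differentiating and early meiotic genes, 9 were higher, 3 of them in all pairs, and 1 was lower in all pairs. Their median was 0.34 (percentile 96.1, pairs 0.13 to 0.33), but after rescaling 1 was higher and 2 were lower in all pairs. The median lay between 0.10 and 0.15 with a floor of 4, scaled to reads on genes, thinned or from summed reads. Dmc1, a meiotic recombinase, was higher by 0.84 (pairs 0.23 to 1.52), and Dnmt3b differed by -0.71 (pairs -1.27 to 0.17). Of 19 prospermatogonial genes, which serve the piRNA pathway and DNA methylation, 14 were higher, 6 in all pairs and none lower in all pairs. The median was 0.28 (percentile 92.7, pairs -0.03 to 0.56), and 0.15 after rescaling, with Tdrd9 at 1.08 (pairs 0.34 to 1.72). All 12 measured p53 and apoptosis genes were higher, but 3 of them in all pairs (median 0.28, percentile 92.1, 0.47 without KO set A and 0.18 after rescaling). Pan germ cell genes had a median of 0.02, which was 0.51 without KO set A and -0.16 after rescaling. In this list Mael, a piRNA pathway gene, was higher (0.62, pairs 0.38 to 0.77).

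Cell cycle genes varied between sets of the same label. The 21 genes of G2 and mitosis had a median of -0.33 that ran from -1.82 to 0.97 over pairs and turned to 0.60 without KO set A, and was -0.57 after rescaling. Their mean level was 1.56 in KO set A, 3.73 in set B and 4.29 in set C, and 3.19 and 3.79 in WT P3. The S phase median was 0.14 (pairs -1.57 to 1.16), 0.89 without KO set A and -0.07 after rescaling. Medians of the remaining lists were 0.16 for pluripotency, 0.18 for retinoid, -0.05 for migration, 0.06 for glycolysis, 0.06 for oxidative phosphorylation and 0.19 for stress genes, each with pairs of both signs. Without KO set A these were 0.09, 0.10, 0.14, 0.17, 0.33 and 0.37, and after rescaling they were 0.12, 0.12, -0.14, 0.03, -0.11 and 0.03. Klf4 was higher in all pairs (0.96, pairs 0.54 to 1.67), and in the oxidative phosphorylation list Cox5a was too (0.99, pairs 0.34 to 1.44). The Rhox cluster list, in which near-identical copies can share reads, had a median of 0.46 over 5 genes, with Rhox5 at 0.72 (pairs 0.21 to 1.41).

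Markers of other cell types also moved with the sets. The 3 measured Sertoli cell markers, Clu, Wt1 and Sox9, had a mean level of 2.16 in KO set A against 0.53 and 0.55 in KO sets B and C and 1.26 and 0.90 in WT P3. Their median difference was 0.05, and -0.39 without KO set A. Des, the measured myoid or stromal marker, differed by 0.49, 4 endothelial genes by a median of 0.15, and 2 leukocyte genes by -0.56. No Leydig or erythroid marker was measured. In the same set Zbtb16, which encodes the progenitor factor PLZF, was above 1 RPM in 23.8% of cells (8.22% to 47.2%), and in 100% of cells of KO sets B and C.

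Across 4932 genes with a mean level of at least 2, 22.3% had the same sign in all 6 pairs, near the 20% that chance gives: 17.6% were higher and 4.68% lower. Other splits of the same 5 sets gave as many genes or more, as 3 of the other 9 exceeded the labelled split and the highest, KO sets B and C against the rest, reached 38.3%. Without KO set A the share was 52.3% of 5024 genes, against 33.3% by chance and 29.5% for the higher of the other 2 splits. That share is on the deposited scale and was not recomputed after rescaling. Mean RPM summed over genes was 143122 and 141532 in KO sets B and C against 119560 and 108513 in WT P3 sets A and B. A shift of the scale can therefore put genes on the same side. With all 5 sets, the median of all genes was 0.14 on the deposited scale and -0.01 after rescaling, a shift of 0.16. The split became 10.8% higher and 12.3% lower. Differences of lists are therefore best read against the random lists, whose medians lay near this shift.

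**Figure D2:**
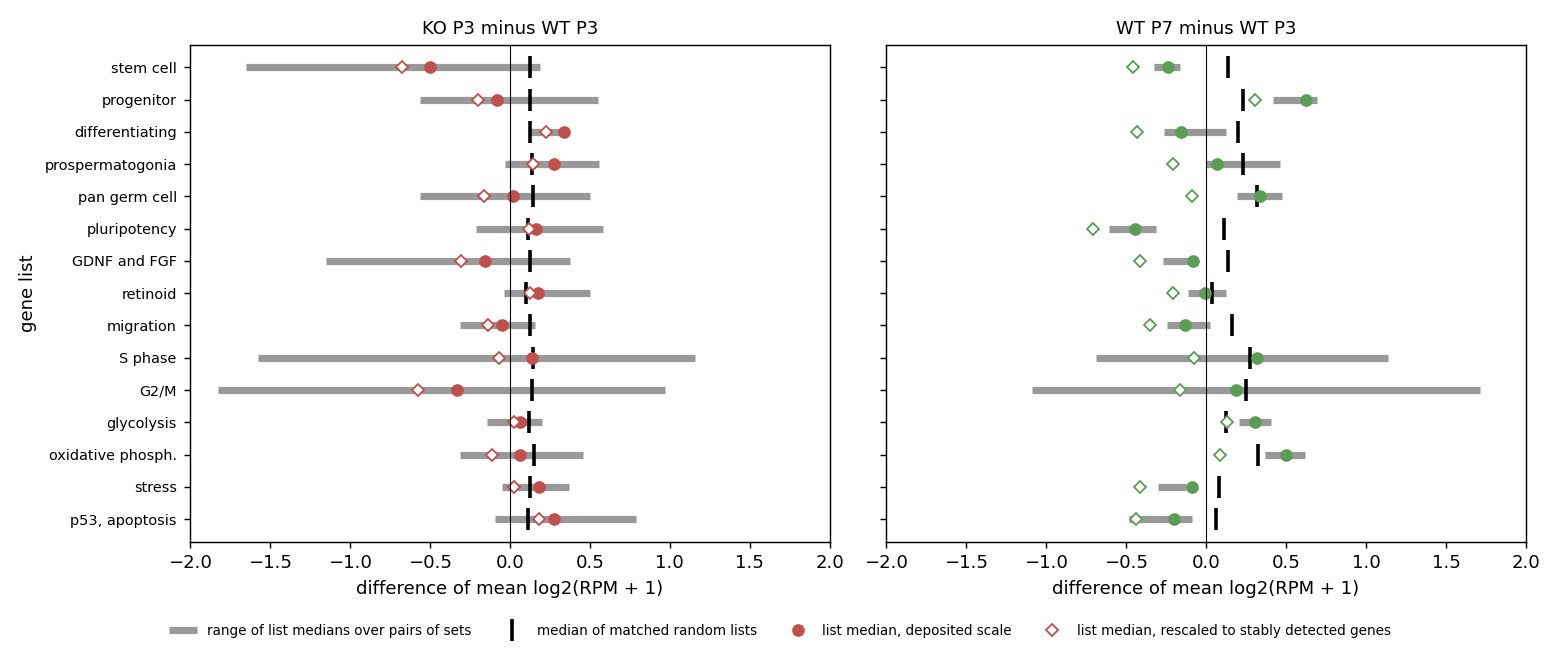
Median difference of mean log2(RPM + 1) on the horizontal axis for 15 gene lists on the vertical axis, for P3 cells labelled KO minus WT P3 (left) and WT P7 minus WT P3 (right). Filled circles are list medians, open diamonds the medians after rescaling to stably detected genes, grey bars the range of list medians over pairs of sets and black ticks the median of matched random lists. The stem cell median is -0.50 on the left with pairs from -1.65 to 0.19, and the progenitor median is 0.63 on the right with pairs from 0.42 to 0.70.

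The comparison of WT P7 with WT P3 describes how cells sorted on the Id4 reporter differed between the 2 ages. Each age has its own sets, so age cannot be told apart from other differences between those sets. Zbtb16 was higher at P7 by 2.28 (pairs 1.88 to 2.69), with 63.1 RPM against 10.6, a ratio of 5.95. Brwd3, a bromodomain gene, was higher by 2.81 (pairs 1.81 to 3.81), Arrdc3 by 2.68 (pairs 1.75 to 3.60), and Isyna1, which makes inositol phosphate, by 2.60 (pairs 2.16 to 3.05). Sfrp2, a secreted Wnt modulator, was higher by 2.27, the alanyl-tRNA synthetase gene Aars by 1.98 and Cyc1, cytochrome c1 of respiratory complex III, by 1.90. B4galt1, Bahcc1, Gyltl1b and Bnc2 were also among the highest, between 1.86 and 1.99. Fos, an immediate early gene, was lower at P7 by the largest margin (-3.33, pairs -3.94 to -2.72). The ratio of mean RPM, P3 to P7, was 9.10, and 39.6% of P7 cells were above 1 RPM against 93.0% (84.3% to 97.7%) of WT P3 cells. Sgk1, a kinase gene, differed by -2.47 (pairs -3.49 to -1.46), Anxa2 by -2.10, the MHC class I gene H2-T23 by -2.06, the synaptonemal complex gene Tex12 by -1.98 and the p53 target Pmaip1 by -1.90. Mmp9, a matrix metalloproteinase, differed by -1.89 and Lmna, which encodes lamin A/C, by -1.88. The rest of the 12 lowest were Ptgr1, D15Ertd621e, Pard3 and Dusp18, between -2.25 and -1.93. All 24 kept their sign after rescaling. With a shift of 0.35 in the median of all genes, this was nearly fixed by the choice of genes with large differences.

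Id4 itself was lower at P7 (-1.32, pairs -1.76 to -0.87), and Rhox10 had nearly the same level (-0.11, pairs -0.26 to 0.03). Of 15 measured stem cell genes, 11 were lower, 8 of them in all pairs, and 2 were higher in all pairs. The median was -0.23 (percentile 1.17, pairs -0.33 to -0.16), and -0.46 after rescaling. Tspan8 differed by -1.27 (pairs -1.91 to -0.62), and Nanos2 by 0.53 (pairs 0.05 to 1.00), near the floor. Gfra1, the GDNF co-receptor, was at 0.42 (pairs 0.08 to 0.75), but 0.03 after rescaling. The list median was positive with 3 other settings, such as 0.25 when RPM was averaged before the logarithm. Progenitor genes were higher, 7 of 12 in all pairs and 2 lower in all pairs. The median was 0.63 (percentile 98.2), and 0.30 after rescaling. Glis3 was higher by 1.16 (pairs 0.77 to 1.56), whereas Cdh1 (-1.32, pairs -1.95 to -0.69) and Lin28a (-0.49, pairs -0.72 to -0.27) were lower.

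Differentiating genes were mixed at P7, with 3 of 11 higher and 4 lower in all pairs (median -0.16, pairs -0.26 to 0.12). The median was 0.11 without WT P7 set A and -0.43 after rescaling. The meiotic gene Hormad1 was lower (-1.76, pairs -2.44 to -1.08), and so was Kit, a receptor of differentiating spermatogonia (-0.99, pairs -1.82 to -0.16), although its mean RPM was nearly the same (9.08 at P7 and 9.43 at P3), while Sohlh2 was higher (0.95, pairs 0.44 to 1.45). The prospermatogonial median of 0.07 had no stable sign, as it was -0.20 after rescaling. Tdrkh was higher (1.29, pairs 0.76 to 1.83) and Piwil4 lower (-0.87, pairs -1.14 to -0.59). Pan germ cell genes had a median of 0.34, close to random lists (percentile 52.6), and -0.08 after rescaling, with 4 higher and 4 lower in all pairs. Dnd1 and Nanos3 were higher, by 1.28 and 1.05. Of 8 pluripotency genes, 6 were lower in all pairs and none higher (median -0.44, percentile 0.450, -0.71 after rescaling, and 0.049 when RPM was averaged before the logarithm), with Dppa4 at -1.31 (pairs -1.86 to -0.77).

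Of 27 oxidative phosphorylation genes, 21 were higher at P7 in all pairs and 2 lower (median 0.50, percentile 88.8). After rescaling the median was 0.09, with 14 higher and 6 lower in all pairs. Ndufv1, a subunit of complex I, was higher by 1.34 (pairs 1.17 to 1.51). The glycolysis list split, as Gpi1 (1.22) and Aldoa (1.17) were higher and Ldha (-1.54) and Hk2 (-0.93) lower in all pairs, with a median of 0.31 (0.13 after rescaling). Among 15 stress genes 7 were lower in all pairs and 2 higher (median -0.09), against 9 lower and 0 higher after rescaling (median -0.41), a median of 0.0087 with a pseudocount of 10, and Fosb differed by -1.65 (pairs -1.75 to -1.54). The p53 and apoptosis median was -0.20 (-0.44 after rescaling, and 0.25 when RPM was averaged before the logarithm), with Pmaip1 lower and Bax higher (1.03, pairs 0.96 to 1.09). GDNF and FGF genes had a median of -0.08, with Spry4 at -1.40 (pairs -2.26 to -0.53), migration genes -0.13 and retinoid genes -0.0043. After rescaling these medians were -0.41, -0.35 and -0.20, with 8 GDNF and FGF genes lower and 0 higher in all pairs, and 14 migration genes lower and 3 higher, against 6 and 5 on the deposited scale. The GDNF and FGF median turned positive with 3 other settings, such as 0.26 when RPM was averaged before the logarithm. The S phase median was 0.32 (pairs -0.69 to 1.14) and the G2/M median 0.19 (pairs -1.09 to 1.71), and they were -0.07 and -0.16 after rescaling, with G2/M levels of 2.59 in WT P7 set A and 4.86 in set B.

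The Rhox cluster had a median of -0.11 over 3 measured genes. Of the other cell type lists, the Sertoli marker Clu was lower at P7 (-1.72, pairs -2.17 to -1.26), the leukocyte genes Fcer1g and Cd68 differed by -1.72 and -0.28, and 2 endothelial genes had a median of -0.14. The 1 measured Leydig marker, Star, was at 0.16, and no myoid or erythroid marker was measured. Clu was above 1 RPM in 40.8% of WT P3 cells and 5.66% of WT P7 cells. Whether RNA from other cells lay behind genes lower at P7 was not tested. Across 4895 genes, 55.1% had the same sign in all 4 pairs, 41.98% higher and 13.1% lower, against 33.3% by chance and 25.3% for the higher of the other 2 splits of the sets. The median of all genes was 0.25 and became -0.11 after rescaling, a shift of 0.35, and the split turned to 21.8% higher and 31.2% lower.

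The 2 comparisons were then set against each other, to ask whether the cells labelled KO were nearer to 1 of the ages. On genes that separated the ages in the sets of 1 letter, the cells labelled KO lay at 0.067 between held-out WT P3 (0) and WT P7 (1) cells. The values were -0.036 and 0.170 for the 2 choices of genes, which shared 18 of the 100 higher and 27 of the 100 lower genes. Averaged over both, KO sets A, B and C were at -0.012, -0.020 and 0.235, and the position without set C was -0.016. Across 4956 genes, which are not independent of each other, the correlation of the 2 differences with separate WT P3 sets was 0.035 (Spearman 0.036), and between -0.172 and 0.181 for single KO sets. With shared WT P3 cells it was 0.237 (Spearman 0.232). Simulated unchanged groups with shared controls gave a mean of 0.671, which is no benchmark for it. They were drawn from both WT P3 sets alike, so they hold no real differences and no variation between sets. The covariance was 0.0592 against a simulated 0.0326, a difference of 0.0266, and 0.0082 with separate sets. The simulated covariance covers sampling of cells only, so the 0.0266 does not measure a link between the 2 differences.

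**Figure D3:**
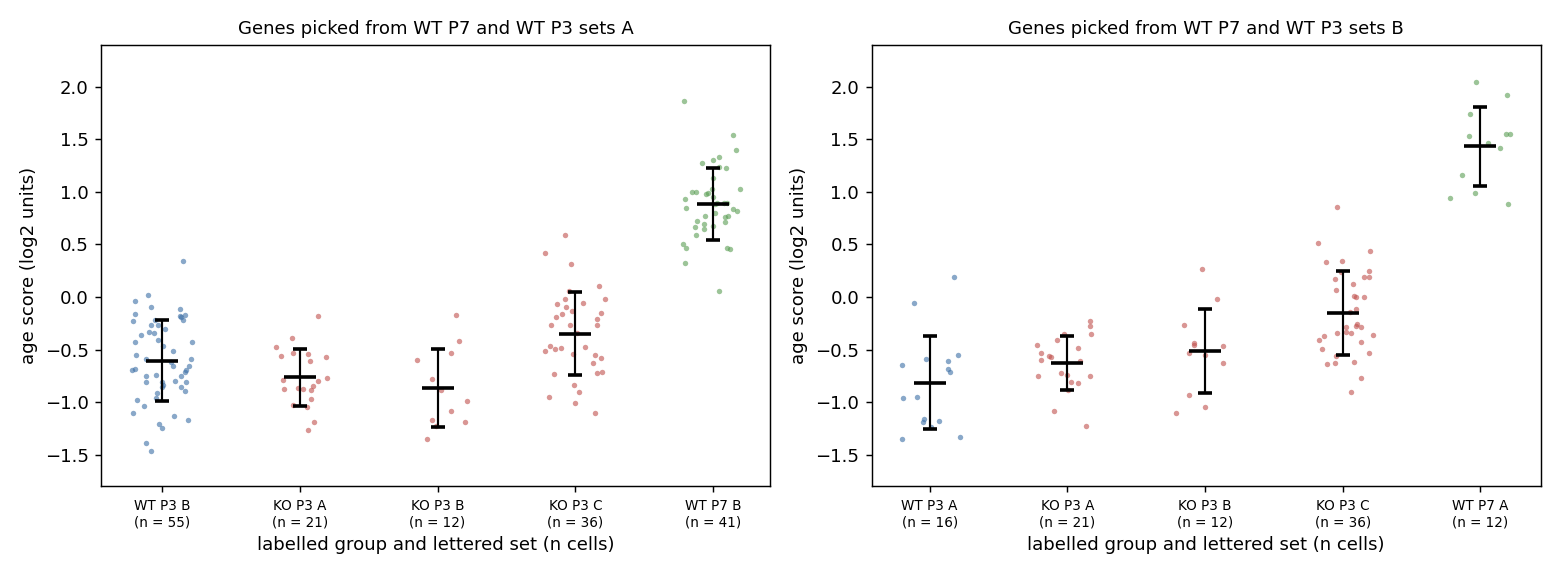
Age score of single cells on the vertical axis (mean log2(RPM + 1) of 100 genes higher at P7 minus that of 100 genes lower at P7), with genes picked from sets A (left) or B (right) and cells of the held-out WT sets and the KO sets on the horizontal axis. Points are cells, and black bars are means with 1 SD between cells. In both plots the means of the KO sets lie nearer to WT P3 than to WT P7, with set C the highest of the 3.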

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

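The tests of other cell types behind Id4 and of handling behind Fos were chosen only after those results were seen. The row of ribosomal RNA precursor, Rn45s, was outside the gene comparisons and stood above the WT P3 level. Its mean RPM over cells was 1.70 times the WT P3 mean in WT P7, where both sets exceeded both WT P3 sets. In the cells labelled KO it was 1.18 times the WT P3 mean, again with each of the 3 sets above both WT P3 sets. RPM summed over genes was higher too, with means of 138140 in cells labelled KO and 153896 in WT P7 against 111002 in WT P3. Rn45s was not rescaled, so its ratios include this shift of the scale. The ratio of 1.18 does not show a rise relative to the genes.

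Rhox10 reads were present in cells labelled KO. Reads shared exactly with other annotated genes are argued against, as 0% of the 714 distinct windows of 50 bases in the annotated Rhox10 transcripts occur in transcripts of other genes. Copies that differ by a few bases and unannotated copies were not searched, so reads borrowed from those stay open. A wrong label on sets A and B stays open: on genes chosen from KO set C and 1 WT P3 set, mean positions between WT P3 (0) and held-out cells of KO set C (1) were -0.375 for KO set A and 0.460 for KO set B over 50 random halvings. With genes chosen against WT P3 set A the positions were -1.15 and 0.154, and against WT P3 set B 0.40 and 0.766, which keeps the test from deciding, and in both sets Id4 was below both WT P3 sets. A transcript left by a partial deletion and the genotype itself also stay open and were not tested, since the removed part is not stated.

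Id4 was lower in the cells labelled KO. A larger share of RNA from other cells would lower germ cell genes alike, which is argued against for KO sets B and C, where the pan germ cell median against WT P3 was 0.51 (SD 0.42 over 9 genes) and Id4 differed by -1.28. Both values are on the deposited scale and were not recomputed after rescaling. A shift of the scale would move both the same way. For KO set A a larger share of RNA from other cells stays open. There the median was -0.48 (SD 0.56) and Id4 differed by -2.47. Sertoli markers were 2.16 against 1.26 and 0.90 in WT P3 sets A and B. Ddx4 and Dazl are named here as germ cell markers rather than by the rule. In KO set A, Ddx4 was 6.75 against 7.67 and 7.77 in WT P3 sets A and B, but Dazl 8.99 against 9.08 and 9.24. Lower depth and the scaling are argued against by their direction. Median reads on genes were 608841 in cells labelled KO and 514921 in WT P3. The deposited scale shifted genes of the cells labelled KO up by 0.16 at the median. Neither correction was therefore likely to shrink the difference. It was -1.89 after thinning to 100000 reads on genes and -1.90 after rescaling to stably detected genes. The genotype and the unstated sort gates stay open, and neither was tested.

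Fos was lower at P7. Depth is argued against, as median reads on genes were nearly equal, at 507865 in WT P7 and 514921 in WT P3. Thinning was therefore unlikely to shrink the difference, which was -3.67 after it. Handling of the cells cannot be told apart from age, as the labels give no record of it. The other 14 measured stress genes had a median of -0.060, with 2 higher and 6 lower in all pairs, but -0.40 after rescaling, with 0 higher and 8 lower. Fosb (-1.65) and, named after their values were seen, Dusp1 (-1.15) and Jun (-0.96) were lower in all pairs, while Egr1 ranged from -0.82 to 0.81 over pairs. Age remains an open explanation.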

How the results depend on the processing

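Scaling to reads on genes, thinning to 100000 reads on genes and summing reads per set were chosen after seeing the data. For the main list medians, the position, the correlation and the shares of cells, 133 values under alternatives moved by less than 1 SD over pairs of sets (shares stayed within their interval), 44 moved by more and 8 changed the sign of a difference that had been the same in all pairs. For single genes and other lists these numbers were 2599, 376 and 12. A difference whose pairs had both signs can change sign within 1 SD, as the stem cell median, KO minus WT, did without KO set A. The cause was not tested. For single genes, values without a set moved by less than 1 SD by construction and say nothing of stability. They are nevertheless part of the 2599. Both 133 and 2599 include values that an alternative could not change, such as P7 minus P3 after dropping a cell labelled KO. These numbers therefore overstate stability. The filters for 2000 genes and for Ddx4 or Dazl removed 0 cells, tested nothing and are left out of these numbers. Genes near 1 RPM are the least certain at this depth. With pseudocount 0.1, the differentiating median, KO minus WT at P3, was 0.45, and at P7 minus P3 the stem cell median was -0.78, the prospermatogonial median -0.016 and Stra8 -0.18. With pseudocount 10 the differentiating median (KO minus WT) was 0.16, and at P7 minus P3 the stem cell median was 0.0075, progenitor 0.35, GDNF and FGF 0.038 and stress 0.0087. With the log of mean RPM, P7 minus P3 gave 0.25 for stem cell, 0.16 for differentiating, 0.53 for prospermatogonial, 0.049 for pluripotency, 0.26 for GDNF and FGF and 0.25 for p53 genes. The differentiating median, KO minus WT, was 0.22 with equal weight per cell, 0.23 after rescaling to stably detected genes, 0.10 with a floor of 4, 0.14 scaled to reads on genes, 0.15 thinned and 0.15 with summed reads. For P7 minus P3, rescaling gave -0.46 for stem cell, 0.30 for progenitor, -0.43 for differentiating, -0.20 for prospermatogonial and -0.084 for pan germ cell genes. No floor gave -0.088 for stem cell, 0.27 for progenitor and -0.094 for prospermatogonial genes. A floor of 4 gave 0.085 for stem cell, 1.12 for progenitor, -0.62 for differentiating and 0.095 for GDNF and FGF genes. Scaling to reads on genes gave -0.46, 0.30, -0.45, -0.23 and -0.10 for stem cell, progenitor, differentiating, prospermatogonial and pan germ cell genes, and -0.00064 for Dnajb1. Thinning gave -0.57, 0.26, -0.40, -0.32 and -0.13 in the same order, and -0.051 for Gfra1. Summed reads gave -0.079 for stem cell, 0.30 for progenitor and -0.36 for differentiating genes.

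Leaving out each set gave, for KO minus WT, -0.71 to 0.21 for stem cell genes (positive only without KO set A), -0.38 to 0.085 for progenitor, 0.24 to 0.40 for differentiating and 0.15 to 0.33 for prospermatogonial genes. For P7 minus P3 the ranges were -0.27 to -0.26, 0.49 to 0.67, -0.22 to 0.11 and 0.026 to 0.30. The correlation ranged from -0.029 to 0.086 and the position from -0.016 to 0.11, with no value where a WT P3 set (for the position, any WT set) was left out. The position was 0.184 with a floor of 4 and -0.056 with 50 genes each way.

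Shares of cells follow their threshold. Rhox10 was above 0 RPM in 95.2% of cells of KO set A, 91.7% of set B, 52.8% of set C, and 68.8% and 76.4% of WT P3 sets A and B. Above 10 RPM it was found in 38.1%, 50% and 2.78% of KO sets A, B and C and in 12.5% of WT P3 set A, and in no cell of the 55 in WT P3 set B. Id4 was above 0 RPM in 79.7% of cells labelled KO and 97.2% of WT P3 cells, and above 10 RPM in 17.4% and 57.7%.

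The letters were not taken as pairing the sets, as the labels do not explain them and only 2 letters occur in all groups. Deviations of sets of the same letter from their group means correlated, across genes, by 0.311, 0.178 and 0.223 for A and by 0.046, 0.178 and 0.120 for B. The 0.178 is that of WT P3 and WT P7. It is the same for both letters by construction, as each of these groups has 2 sets. With the letter as a block KO set C has no partner and drops out, and KO minus WT gave medians of -0.70 for stem cell, -0.076 for progenitor, 0.40 for differentiating and 0.28 for prospermatogonial genes, nearly the medians without that set, and a correlation of -0.018, while the P7 medians were those without the block.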

Other observations

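The gene families in this part were chosen after seeing the data. Of 35 proteasome genes, 26 were higher at P7 and 3 lower in all pairs, with a median at P7 minus P3 of 0.71 (percentile 99.92), and Psmd7 at 1.62 and Psmb10 at -0.26. Of 51 cytosolic ribosomal protein genes, 40 were higher and 4 lower in all pairs (median 0.58, percentile 99.86), from Rpl37 at -1.28 to Rpl13a at 1.58. All 8 measured genes of the chaperonin that folds actin and tubulin were higher in all pairs (median 0.80, percentile 96.0), with Cct5 at 1.34. After rescaling to stably detected genes these medians were 0.30, 0.19 and 0.38. The 17 aminoacyl-tRNA synthetase genes had a median of 0.42 (percentile 80.0) and 0.05 after rescaling, and 9 lysine demethylase genes 0.51 (percentile 82.4) and 0.09.

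In the cells labelled KO, the proteasome median was -0.06 (percentile 0.460, pairs -0.53 to 0.32), with Psmb10 at -0.90. All 9 lysine demethylase genes were higher, 3 of them in all pairs, with a median of 0.42 (percentile 95.5, and 0.24 after rescaling) and Kdm3a at 1.18. The ribosomal protein, chaperonin and synthetase medians were 0.18, 0.06 and 0.25, at percentiles 73.6, 22.8 and 81.6.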
